A study of Mus musculus with 8 samples.

How the data were processed

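TIGIT-sorted mouse lung tumour cells were profiled by ATAC-seq in 8 libraries. Per the file headers, the deposited values are raw counts of read pairs per peak from featureCounts 2.0.0, with a pair allowed to count for more than 1 overlapping peak. The BAM file names in that header carry marks for merged runs, removal of duplicates, removal of mitochondrial reads and filtering. Of these names 1, that of the TIGIT-positive library of animal 2, also carries a mark for trimming. Per the submitters' processing notes, SAMtools 1.8, MACS2 2.2.6 and bedtools 2.26.0 were used on the mm10 build. The aligner, any shift of read ends for the transposase offset, and whether peaks were called per library or on pooled reads are not given in the sources used here. The deposited peak list holds the same 112729 intervals as the count table, without scores. Peaks were called on the same libraries that were compared, and counts in peaks are not library totals of mapped reads. All values start from these counts, and no reads were processed.

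Groups came from the sample titles. The titles also give animal numbers, each of which occurs once in either gate, so libraries are paired by animal. The pairing was checked before calls were compared: deviations from the group means correlated with r of 0.76, 0.47, 0.58 and 0.53 within animals 1 to 4 and of -0.52 to 0.14 between animals. No 2 libraries of a group agreed within sampling noise, with chi-square per degree of freedom of 2.57 to 7.05. The comparison, its main design without a block, the alternatives, the gene lists and the rule for named peaks were fixed before the data were examined.

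Peaks were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, with TMM scaling and filterByExpr, which left 111713 peaks and removed 1016. P-values were adjusted by Benjamini-Hochberg and called at 0.05. The main design held the gate alone, and the fit with the animal as a block was set beside it in advance. The SE of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.225 without the block and 0.068 with it. CPM values use TMM-scaled library sizes and are means with SD over 4 libraries. The p-values and SE of peaks in the fit with the block rest on the spread of within-animal differences, which edgeR pools in part over peaks. They therefore do not measure the spread between the 4 animals at a single peak. At the Slc34a2 peak the differences were -0.888, -1.523, 0.068 and -0.946 in animals 1 to 4, with an SE of 0.1. P-values without the block rest on the spread between libraries of a gate, pooled likewise, and ignore the pairing. Camera with a preset correlation compares the peaks of a list with other peaks, and Fisher's test counts peaks, so neither measures the spread between animals.

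Gene positions came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with gene spans but no strand, exons or sequence. The planned assignment by transcription start was therefore replaced: a peak belongs to the protein-coding gene whose span is nearest, within 100 kb, and "gene end" means either end of a span. Whether a peak inside a gene is exonic or intronic was not determined. The planned motif test and GC correction need a genome sequence and were not run. Nearness does not show which gene a peak acts on. All 510 entries of the 27 lists matched a gene of the table.

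Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 27 lists, with an estimated correlation and fry as alternatives. Peaks named in the text follow 1 rule. They are the 12 called peaks per direction with the largest change, 1 per gene, among those with 1 direction in all 4 animals, the 10 genes per direction with most called peaks, up to 4 members per list with the smallest p, and all peaks at Tigit. Because the fit without a block called 0 peaks, the rule was applied to the fit with the block, as it provides, and "called", "higher" and "lower" refer to that fit. Shares of counts per chromosome were compared by an exact permutation of the 70 assignments of labels, two-sided. The position of called peaks was compared by Fisher's exact test, also against up to 5 uncalled peaks per called peak drawn within 20 bins of abundance.

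Alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2, total counts, loess offsets over abundance (span 0.3), no filter, a mean of at least 50 counts, autosomes only, an adjusted p of 0.1, a 2-fold minimum, other windows around genes, and leaving out each library or pair. Counts with the variation of this comparison were drawn independently for each peak from the count model of edgeR, and 111054 simulated peaks were tested. Changes were placed only in peaks with a mean of at least 50 counts, a filter that left 59659 peaks of the data. The fit without a block recovered 0% of 67 peaks changed 1.25-fold, 0% of 67 changed 1.5-fold and 15.15% of 66 changed 2-fold. The fit with the block recovered 25.37%, 64.18% and 98.48%, with 7 of 110854 unchanged peaks called. Recovery in weaker peaks was not measured, and counts drawn from this model cannot show how many calls in the data are false. In simulated lists of 100 peaks drawn at random, both designs recovered 5 of 5 lists shifted by 0.2 on the log2 scale and called 0 of 15 others. Beyond the animal means, the peaks of these simulated lists were not correlated. In the data the estimated correlation with the block was 0.037 for AT2 identity and 0.052 for the high-plasticity list. The simulation therefore does not show how often the preset correlation gives false calls in such lists. Depth of 13182166 to 18188658 counts over 112729 peaks leaves weak peaks with few counts, and changes there were measured with larger errors.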

Results

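Chromatin accessibility was measured by bulk ATAC-seq, in which a transposase cuts and tags open DNA, in mouse lung tumour cells of alveolar type 2 (AT2) origin. The tumours were Kras-mutant and Trp53-null. Cells were sorted by flow cytometry on TIGIT, a receptor best known from T and NK cells, and the series title places the sort in a study of a high-plasticity state in lung cancer. The 8 libraries formed 4 TIGIT-negative and 4 TIGIT-positive samples, 1 of each from every animal number. The animals are called 1 to 4 here. The title of animal 3 joins 2 animal numbers, and whether it is a pool was not stated. Counts were given for 112729 peaks (mm10). In animals 1 to 4 the TIGIT-negative libraries held 18171782, 14974430, 17111158 and 17000471 counts in peaks, and the TIGIT-positive libraries 13182166, 18188658, 15656364 and 16071800.

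The animal of origin separated the libraries more than the gate did. Animals accounted for 71.9% of the sum of squares of log2 CPM (counts scaled to library size), the gate for 11% and the rest for 17%. These shares are not divided by degrees of freedom, of which the animals and the rest each have more than the gate. The gate's smaller share than the rest thus does not make it smaller per degree of freedom. The first principal component took 44.7% of the variance and set both libraries of animal 1, at -121.4 and -165.7, apart from the other 6, at -1.3 to 76. The second component took 18.2%. In each animal the TIGIT-positive library lay above the TIGIT-negative library on the second component and below it on the first. It also lay above on the fourth, which took 8.6%. Within-animal differences between the gates correlated across peaks with r of 0.08 to 0.31 between animals, and peaks are not independent replicates.

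**Figure D1:**
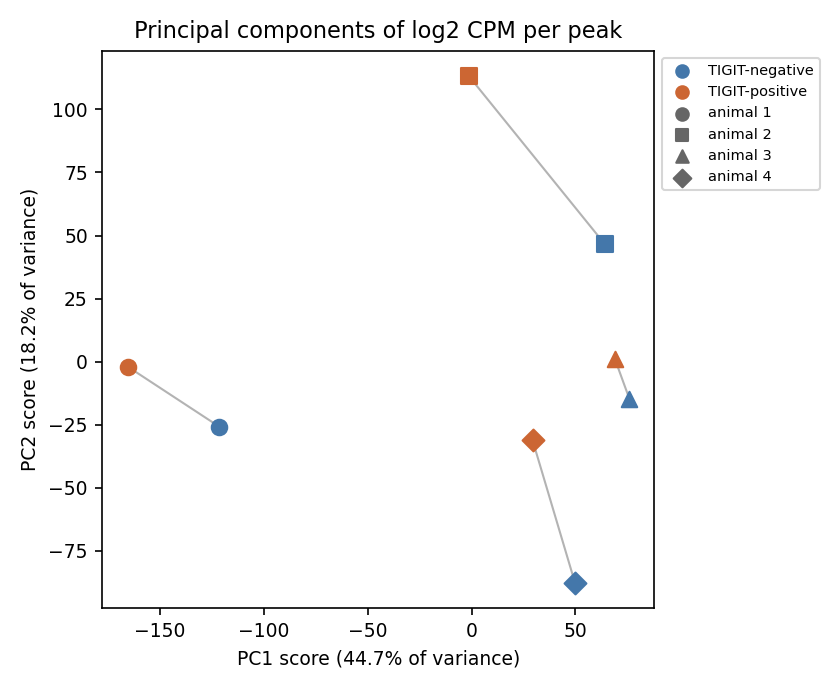
Scores of the 8 libraries on the first and second principal components of log2 CPM over 111713 tested peaks, with colour for the gate, symbol for the animal and a line joining libraries of 1 animal. Both libraries of animal 1 lie below -121 on the first component, and the line of every animal rises on the second from the TIGIT-negative to the TIGIT-positive library.

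The comparison of the gates first serves as a check on the sort, at the Tigit gene itself. Tigit spans chromosome 16 from 43626137 to 43665125, and 8 tested peaks lay within 50 kb of it. The 3 peaks nearest to Tigit were more accessible in TIGIT-positive cells in the fit with animals as a block. The peak inside the gene at 43654741 to 43655922 had 8.43 ± 1.79 CPM (SD, n = 4) in TIGIT-negative and 11.55 ± 3.38 CPM in TIGIT-positive cells, a log2 fold change of 0.44 ± 0.11 (SE; adjusted p = 0.0125). The peak over a gene end at 43663488 to 43665855 rose by 0.39 ± 0.09 (adjusted p = 0.00963), and the peak 32367 bp outside the gene at 43697492 to 43699765 by 0.38 ± 0.09 (adjusted p = 0.00986). Adjusted over the locus alone, 5 of the 8 peaks passed, the other 2 lying inside the neighbouring gene Zbtb20 with log2 fold changes of 0.67 and 0.80. Animal 3 had the smallest differences at the 3 Tigit peaks, of 0.11, 0.01 and -0.10. Without the block 0 of the 8 peaks passed either adjustment in edgeR (smallest adjusted p over the locus alone = 0.131), with 2 at an unadjusted p under 0.05, both in Zbtb20. With the block but without animal 2 or without animal 4, 0 peaks passed over all tested peaks, and without animal 1 the count was 1.

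**Figure D2:**
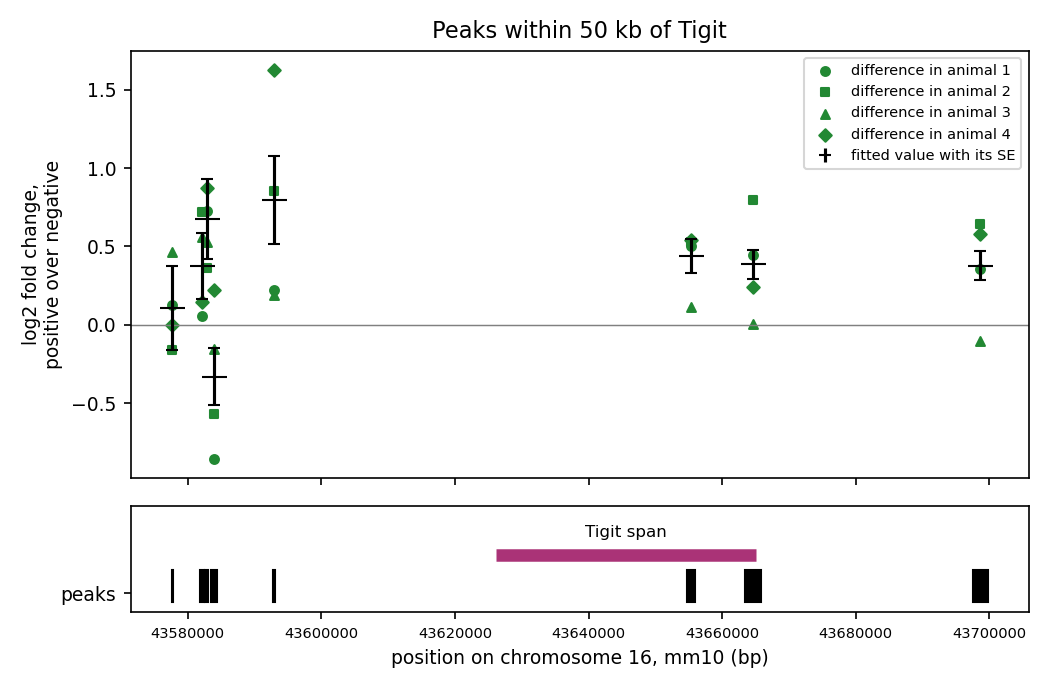
Log2 fold change of TIGIT-positive over TIGIT-negative cells for the 8 peaks within 50 kb of Tigit against position in bp on chromosome 16 (mm10), with the gene span and peak widths to scale below. Black marks are values fitted with animals as a block with their SE, green symbols the 4 within-animal differences, and the 3 peaks at the right stand at 0.44, 0.39 and 0.38.

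Across the genome, with the animals as a block, TIGIT-positive cells had lower accessibility at single peaks of the AT2 genes Slc34a2, Napsa and Abca3 and higher accessibility at single peaks of Cd44, Itga2, Runx1 and Foxp1. The AT2 identity list had 0 higher and 19 lower called peaks, while the lists that hold the latter genes went both ways. The high-plasticity list had 12 higher and 2 lower, the RUNX and TEAD-YAP list 4 and 6, and the lung lineage transcription factors 8 and 6. The last 2 lists had 1.45% and 2.59% of their peaks higher and 2.17% and 1.94% lower. Over all tested peaks these shares were 1.56% and 1.61%, so Runx1 and Foxp1 do not stand for a result of their lists. Whether any peak passed depended on the pairing by animal. In the planned edgeR quasi-likelihood fit without a block, 0 of 111713 tested peaks passed a Benjamini-Hochberg adjusted p of 0.05, with 3090 at an unadjusted p under 0.05, and DESeq2 and limma-voom also gave 0, with 2423 and 3303 at an unadjusted p under 0.05. With the animal as a block, 3547 peaks passed in edgeR, of which 1747 were higher and 1800 lower in TIGIT-positive cells, 3.18% of those tested. Their median absolute log2 fold change was 0.48, with a range from -1.75 to 1.48, and 3198 kept 1 direction in all 4 animals. Of the 3547, 3263 lay within 100 kb of a protein-coding gene, at 2577 genes in all. Scaling by total counts moved the split to 2074 higher and 1328 lower. The count was 55 with the block in DESeq2, 317 without animal 2 and 313 without animal 4, while limma-voom with the block gave 3417.

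The direction of the calls was checked in an animal that had not been used to make them. Of the peaks called from the other 3 animals, 83.5% of 2358 had the same direction in animal 1, 94% of 317 in animal 2, 73% of 4747 in animal 3 and 92.7% of 313 in animal 4. Over all tested peaks these shares were 60.5%, 65.1%, 56.8% and 62.9%. The median change in the called direction in the left-out animal was 0.22, 0.63, 0.13 and 0.31 on the log2 scale, so animal 3 had the smallest.

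Peaks with the largest rise in TIGIT-positive cells lay at Lama3, a laminin chain of epithelial basement membranes, Smad2, a transcription factor of TGF-beta signalling, and Foxp2, a forkhead factor of the airway epithelium. The Lama3 peak (chromosome 18, 12481403 to 12481650, inside the gene) had 0.39 ± 0.26 CPM in TIGIT-negative and 1.09 ± 0.52 CPM in TIGIT-positive cells (SD, n = 4), a log2 fold change of 1.48 ± 0.36 (adjusted p = 0.0102). The Smad2 and Foxp2 peaks changed by 1.30 ± 0.36 and 1.27 ± 0.36 (adjusted p = 0.0301 and 0.0307). Kcnip1, Ccdc91, Polr3g, Map3k13, Riok1, Ate1, Cd44, Anks6 and Il16 followed, at 1.26 to 1.15. These 12 peaks had mean values under 2 CPM in both groups, so their fold changes carry large errors. Genes with the most higher peaks were Mtcl1 with 5 of 28 tested, then Foxp1, Iqsec1, Baz1a, Tnfaip8, Slc25a21, Bcas1 and Adgrv1 with 4, of which Iqsec1 also had 1 lower peak, and Lrrc28 and the WNT ligand gene Wnt7a with 3. These 10 genes had 11 to 93 tested peaks each, most at Foxp1, and medians over all their peaks from -0.01 at Mtcl1 to 0.30 at Baz1a. The Foxp1 peak on chromosome 6 (98865816 to 98866691, 58651 bp from the gene) went from 6.32 ± 0.75 to 10.55 ± 2.91 CPM, a log2 fold change of 0.72 ± 0.12 (adjusted p = 0.000245). The Wnt7a peak inside the gene (chromosome 6, 91372255 to 91373364) changed by 0.69 ± 0.12 (adjusted p = 0.000388), and both libraries of animal 1 lay far above the others there.

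The largest losses lay at Susd6 (chromosome 12, 80795443 to 80795861), which went from 1.54 ± 0.55 to 0.45 ± 0.15 CPM, a log2 fold change of -1.75 ± 0.32 (adjusted p = 0.000572), at the diacylglycerol kinase gene Dgkg, with -1.61 ± 0.33 (adjusted p = 0.00212), and at Nkd1, a WNT pathway antagonist, with -1.57 ± 0.31 (adjusted p = 0.00138). Gm45915, Skil, Rhbdd2, Wnt8b, Mrps9, Ryr2, Fads2b, Agxt and Fam53b followed, at -1.47 to -1.30. These 12 peaks had means of at most 2.75 CPM in TIGIT-negative and 1.09 CPM in TIGIT-positive cells, so their fold changes also carry large errors. The integrin gene Itga9 and the Rho GTPase-activating gene Dlc1 had most lower peaks, with 5 each. Slc34a2, Sorcs2, Atp1a1, Lrmda, Tle3, Elfn1 and Tbc1d30 had 4 and Tns1 had 3, and Lrmda also had 1 higher peak. These 10 genes had 14 to 45 tested peaks each, and medians over all their peaks from -0.18 at Dlc1 to 0.04 at Lrmda. The Sorcs2 peak (chromosome 5, 36389343 to 36391146) went from 32.8 ± 6.94 to 22.4 ± 7.16 CPM, a log2 fold change of -0.57 ± 0.08 (adjusted p = 1.22e-05). The Tns1 peak changed by -0.83 ± 0.14 (adjusted p = 0.000231).

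Peaks called near genes of AT2 identity were lower in TIGIT-positive cells. Of the 18 list genes with tested peaks, 12 had only lower peaks among those called, 0 had a higher one and 6 had none. By peak, 19 of 185 were lower (10.27%, against 1.61% of all tested peaks) and 0 higher. Adjusted over the list alone, 28 were lower and 4 higher. The club and secretory list, which was not called, had as large a share of lower peaks, 10.53%, but also 7.02% higher. The peak over Slc34a2, the sodium-phosphate transporter of AT2 cells (chromosome 5, 53067100 to 53074222), went from 29.5 ± 12.3 to 19.2 ± 13.4 CPM, a log2 fold change of -0.71 ± 0.10 (adjusted p = 8.05e-06), lower in 3 of 4 animals. Napsa, an aspartic protease that processes surfactant protein B, changed by -0.38 ± 0.07 (adjusted p = 0.000866). Dram1 changed by -0.47 ± 0.10 (adjusted p = 0.00241) and Abca3, the lipid transporter of lamellar bodies, by -0.35 ± 0.07 (adjusted p = 0.00242). The list median was -0.10 (quartiles -0.30 and 0.06), with -0.12, -0.22, -0.004 and -0.12 in animals 1 to 4. Camera called the list lower with a preset correlation without the block (adjusted p = 0.00943) and with it (adjusted p = 0.00183). The call was lost with an estimated correlation (adjusted p = 0.861 with the block and 0.979 without), and, without the block, without the TIGIT-negative library of animal 3 or 4 (adjusted p = 0.097 and 0.231) or the TIGIT-positive library of animal 1 or 2 (adjusted p = 0.112 and 0.671). The median of the fit without the block, -0.102, was -0.06 without the TIGIT-negative library of animal 3 or of animal 4, -0.04 without the TIGIT-positive library of animal 2 and -0.165 without that of animal 3.

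Among surface and secreted genes tied to the high-plasticity state, 5 of 19 had only higher peaks among those called, 1 only lower, 1 both and 12 none. Of 212 peaks near 19 genes, 12 were higher and 2 lower (5.66% and 0.94%, against 1.56% and 1.61% of all tested peaks); adjusted over the list alone, 24 were higher and 3 lower. A distal peak of Cd44, the hyaluronan receptor (chromosome 2, 102956077 to 102957441), went from 7.49 ± 4.39 to 10.96 ± 5.38 CPM, a log2 fold change of 0.56 ± 0.12 (adjusted p = 0.00397), with 14.04 CPM in the TIGIT-negative library of animal 1 and at most 5.78 CPM in the other 3. The integrin gene Itga2 changed by 0.42 ± 0.10 (adjusted p = 0.00712), and Lamb3, a laminin chain, had a lower peak at -0.49 ± 0.12 (adjusted p = 0.00758). The list median was 0.135 (quartiles -0.03 and 0.30) and lay above 0 in all 4 animals, at 0.08, 0.21, 0.06 and 0.11. Camera called the list higher without the block (adjusted p = 0.000877) and with it (adjusted p = 0.000573). The call was lost with an estimated correlation (adjusted p = 0.861 with the block and 0.979 without), with gene-end peaks only (adjusted p = 0.206 with the block) and, without the block, without the TIGIT-positive library of animal 1 (adjusted p = 0.176, median 0.072 against 0.139). The list was written from knowledge of the cell state that TIGIT sorting was meant to enrich, so its direction is not independent of the choice of gate. It holds Tigit, and without Tigit the adjusted p was 0.00107.

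**Figure D3:**
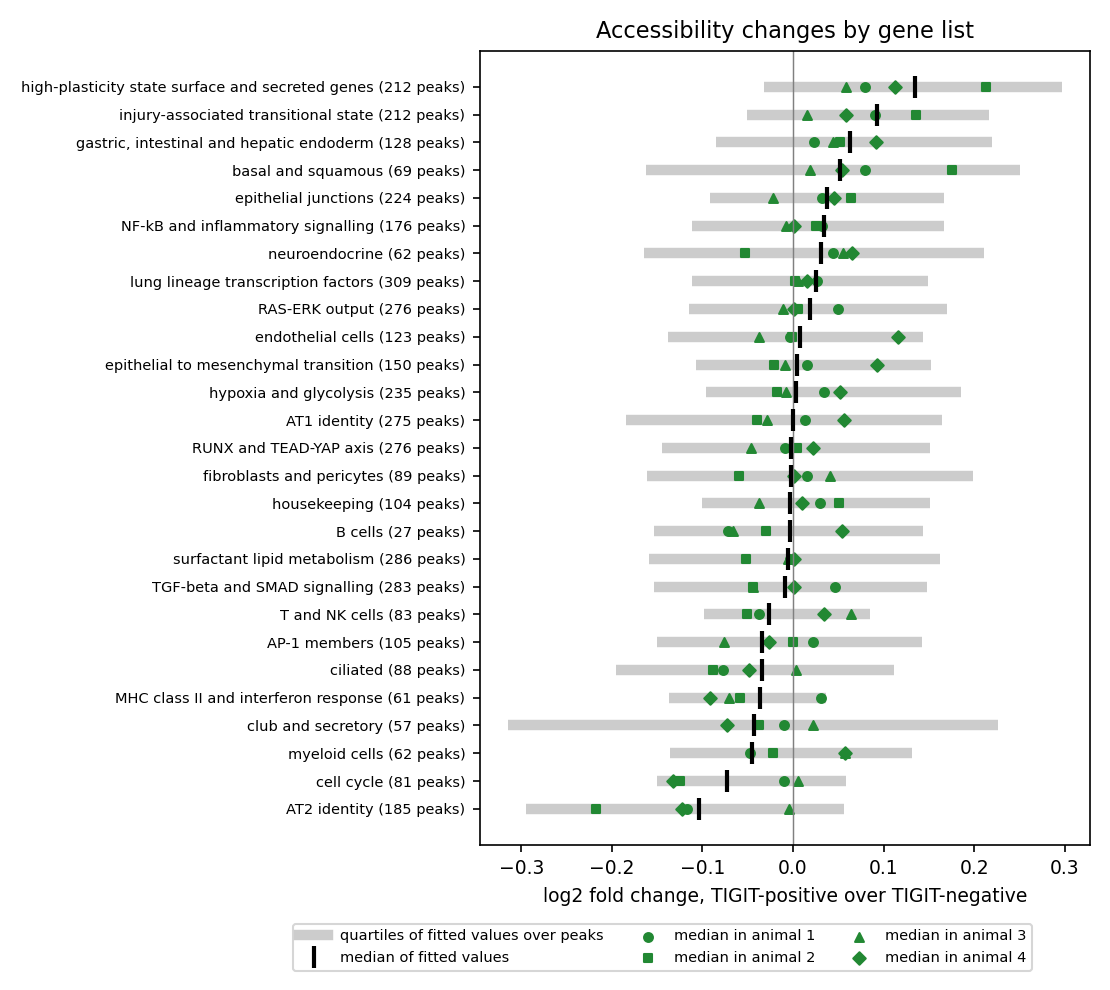
Median log2 fold change (TIGIT-positive over TIGIT-negative, horizontal axis) of the peaks near the genes of each of the 27 lists, as fitted with animals as a block (black) with quartiles over peaks (grey) and as measured in each animal (green). The high-plasticity list lies highest, at 0.135, and the AT2 identity list lowest, at -0.10.

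The other 25 lists were not called in either fit (camera, adjusted p of 0.0937 to 0.974 with the block), though single members passed. Members are named by smallest p, and 1.56% of all tested peaks were called higher and 1.61% lower. Shares higher and lower were 3.77% and 0.94% in the injury-associated list, 1.45% and 2.18% in AT1 identity, and 2.59% and 1.94% in the lineage factors. Genes of the injury-associated transitional state had 8 higher and 2 lower peaks of 212 (11 and 2 adjusted over the list alone) and a median of 0.093. The median of the fit without the block, 0.089, was 0.036 without the TIGIT-positive library of animal 1 and 0.141 without that of animal 3. Peaks near Krt18 and Lgals3, a keratin and a galectin of this state, were higher, at 0.42 ± 0.08 and 0.37 ± 0.07 (adjusted p = 0.000674 and 0.00085), and peaks near Krt7 and Tm4sf1 were lower, at -0.97 ± 0.23 and -1.17 ± 0.31. This list was called higher with loess offsets (adjusted p = 0.0265 with the block) and, without the block, without the TIGIT-positive library of animal 3 (adjusted p = 0.00831), not with an estimated correlation (adjusted p = 0.861). The AT1 identity list, of the flat gas-exchange cells, had 4 higher and 6 lower peaks of 275 (7 and 11 over the list alone). The claudin gene Cldn18 changed by -0.55 ± 0.08 (adjusted p = 2.17e-05) and the homeobox gene Hopx by -0.50 ± 0.10 (adjusted p = 0.00126). Col4a3 and Col4a4 changed by -0.41 ± 0.10 and -0.34 ± 0.09. Lung lineage transcription factors had 8 higher and 6 lower peaks of 309 (11 and 8 over the list alone). Id2 was higher by 0.43 ± 0.10, and Elf5 and Etv5 were lower, at -0.74 ± 0.18 and -0.48 ± 0.12.

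The gastric, intestinal and hepatic endoderm list had 6 higher peaks and 1 lower of 128 (6 and 2 adjusted over the list alone), with a median of 0.063 and an adjusted p of 0.421. The median of the fit without the block was 0.069, and 0.043 without the TIGIT-positive library of animal 1. Tff1 and Gkn2, secreted proteins of the gastric mucosa, were higher by 0.49 ± 0.11 and 0.45 ± 0.12 (adjusted p = 0.00584 and 0.0208), and Hnf4a, a transcription factor of gut and liver, by 0.52 ± 0.14 (adjusted p = 0.0289). Hnf1b was lower, at -0.33 ± 0.09 (adjusted p = 0.0283). The RUNX and TEAD-YAP list had 4 higher and 6 lower peaks of 276 (5 and 8 over the list alone). These 4 and 6 were 1.45% and 2.17% of its peaks, against 1.56% and 1.61% of all tested peaks. Runx1 and Runx2 were higher, at 0.82 ± 0.15 and 0.50 ± 0.10 (adjusted p = 0.000754 and 0.00109), and Vgll4 and Nuak2 lower, at -0.58 ± 0.15 and -0.26 ± 0.07. The AP-1 list had 3 higher and 6 lower peaks of 105 (6 and 8 over the list alone), with Batf at -1.03 ± 0.22, Jdp2 at -0.61 ± 0.14 and Fosb at -0.26 ± 0.06, and a distal Fos peak at 0.32 ± 0.08.

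Markers of other cell types were included because TIGIT is also a lymphocyte receptor. The T and NK cell list had 2 higher peaks and 0 lower of 83, near Ctla4 (0.33 ± 0.10, adjusted p = 0.0404) and inside Cd4 (0.36 ± 0.11, adjusted p = 0.0426), with a list median of -0.03. Adjusted over the list alone these were also 2 and 0. The share called higher was 2.41%, against 1.56% of all tested peaks. The sign of the list median was not stable. The median of the fit without the block, -0.04, was 0.044 without the TIGIT-negative library of animal 3. It was 0.037 without the TIGIT-positive library of animal 1 and -0.08 without that of animal 3. The B cell list had 0 called peaks of 27 and 0 over the list alone. The myeloid list had 1 higher peak, at Mrc1, and 2 lower, at Spi1 and Fcer1g, of 62 (1 and 2 adjusted over the list alone). The endothelial list had 2 lower peaks of 123, near Erg and Tie1 (1 higher and 4 lower over the list alone), and the fibroblast and pericyte list 1 lower of 89, near Col1a1 (0 and 1 over the list alone). The housekeeping list had 0 called peaks of 104 and 0 over the list alone. In the block fit the sign of the list median and of the test differed for the endothelial list (median 0.008, test lower) and for the fibroblast and housekeeping lists (medians -0.002 and -0.003, test higher).

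Called peaks were placed unevenly relative to gene ends. Of the higher peaks, 6.5% lay within 1 kb of an end of a protein-coding gene, against 15.4% of peaks not called (odds ratio 0.38, 95% interval 0.31 to 0.46, two-sided Fisher's exact p = 7.08e-30). Of the lower peaks, 18.8% did (odds ratio 1.28, 1.13 to 1.44, Fisher's exact p = 8.95e-05). Against peaks of like abundance the odds ratio of the higher peaks was 0.27, and that of the lower peaks was 0.91 (0.80 to 1.03, Fisher's exact p = 0.124). Peaks are not independent replicates, so these tests describe this set of peaks.

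Shares of counts per chromosome were compared between the gates without regard to pairing. Median log2 fold changes lay between -0.046 on chromosome 11 and 0.056 on chromosome 13. Chromosome 13 held 4.04 ± 0.08% of counts in TIGIT-negative and 4.19 ± 0.05% in TIGIT-positive cells (SD, n = 4). Its exact permutation p of 0.0286, two-sided, is the smallest that 4 against 4 libraries can give, so a single chromosome cannot pass after adjustment, and 0 did (smallest adjusted p = 0.571). Median within-animal differences had 1 sign in all 4 animals on chromosomes 13, 18 and 19 (higher) and 1, 4 and 11 (lower), and with 4 pairs an exact sign-flip test of these cannot go below 0.125.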

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

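For each measure, the gap of the highest or lowest library of a gate to its nearest neighbour was divided by the range of the 4 libraries. Over 408 such tests, 26 ratios were above 0.829. Chance flags about 1 in 20 groups. Animal 1 was the stray in 18 of the 26, animals 2 and 4 in 2 each and animal 3 in 4.

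The TIGIT-positive library of animal 1 had 105 peaks with 0 counts, against at most 13 in the others of its gate (ratio 0.939), at the lowest total of 13182166 counts. The TIGIT-negative library of animal 1 stood apart on the first principal component (0.867). Chromosome shares strayed for chromosome 2 in the TIGIT-negative library of animal 1, lowest at 7.75% (0.891), for chromosome 3 in the TIGIT-positive library of animal 1, lowest at 4.93% (0.859), and for chromosome 19 in the TIGIT-positive library of animal 2, highest at 3.73% (0.882). Mean log2 CPM of the B cell list was lowest in the TIGIT-positive library of animal 1 (0.923), and that of the gastric, intestinal and hepatic endoderm list in the TIGIT-negative library of animal 4 (0.831).

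Among named peaks, the TIGIT-negative library of animal 1 was highest at Tnfaip8 (0.882), Wnt7a (0.898), Cd44 (0.876), Runx2 (0.885), Dusp5 (0.918) and the distal Tigit peak at 43697492 (0.843). It was lowest at Etv5 (0.897), Acaca (0.941), Uchl1 (0.968) and Nkx2-2 (0.899). The TIGIT-positive library of animal 1 was highest at Wnt7a (0.866) and lowest at Blk (0.896) and at the Zbtb20 peak at 43583536 (0.839). Animal 3 was highest at Agxt in the TIGIT-negative gate (0.887) and at Nkd1 (0.905), Dram1 (0.839) and Lamb3 (0.849) in the TIGIT-positive gate. The lowest TIGIT-positive library was that of animal 2 at Birc3 (0.921) and that of animal 4 at Relb (0.895).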

How the results depend on the processing

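Alternatives that combine the block with another choice were chosen after seeing the data, other than loess offsets and left-out pairs in the peak test and the tests of gene-end placement, as were lists without shared genes. Every alternative without a block gave 0 called peaks, as the planned fit did, leaving out each library included. With the replicate block edgeR called 3547 peaks, and with loess offsets too 3757. It called 3555 with DESeq2 size factors, 3402 with total counts, 3599 with no filter, 3484 with a mean of at least 50 counts, 7025 at an adjusted p of 0.1 and 157 with a 2-fold change, 45 higher and 112 lower. Limma-voom with the block gave 3417 and DESeq2 55. Without pair 1, 2, 3 or 4 the count was 2370, 317, 4750 or 313. The gap between the tools and between the pairs was not explained, and the cause was not tested. All 55 were among the 3547. The 157 are a part of the 3547 by definition, so their overlap is no check. With pair 2 left out 301 of 317 were, and with pair 4 left out 304 of 313. With pair 1 left out 1946 of 2370 were, and with pair 3 left out only 2801 of 4750.

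The 2 list calls fell to 0 with an estimated correlation or fry, with or without the block, and to 1 with gene-end peaks and the block. Gene-end peaks without the block called 2 lists, AT2 identity and cell cycle. Leaving out 1 library gave 0 to 3 lists, and leaving out any pair with the block called both. Over all alternatives run, adjusted p ranged from 0.000252 to 0.979 for AT2 identity and from 8.12e-06 to 0.979 for the high-plasticity list. At Tigit the 0 peaks called without a block became 3 with it, 3 with loess offsets too, and 1, 0, 3 and 0 without pairs 1 to 4. Adjusted over the locus alone, these counts were 5, 5, 4, 5, 5 and 4, and 0 to 2 without 1 library and without the block. The odds ratio of lower peaks at gene ends turned to 0.91 against peaks matched on abundance. Animals took 85.9% of the sum of squares over the 5000 most variable peaks. Chromosome tests passed under 0 alternatives, which says nothing of stability at the smallest p of 0.0286.

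Of the 152 named peaks, 119 passed with the block and 0 without it. With the block 7 passed in DESeq2, 22 without pair 2, 28 without pair 4, 96 without pair 1 and 110 without pair 3. A mean of at least 50 counts gave values for 101 peaks and some left-out libraries or pairs for 150 or 151. Where there was a value, directions held except in 2 cases. The Ptgs2 peak ranged from -0.007 to 0.665 with 1 library left out, and the Zbtb20 peak at 43577603, not called, was at -0.008 without pair 3. Motif tests and GC offsets were not run for want of a genome. Without a block, tests of gene-end placement gave no value, since 0 peaks were called.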

Other observations

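Further gene groups had called peaks in both directions without a list call. Over all tested peaks 1.56% were called higher and 1.61% lower, and members are named by smallest p. In the surfactant lipid list 6 peaks were higher and 8 lower of 286 (11 and 11 adjusted over the list alone). Pparg, a regulator of lipid genes, changed by 0.52 ± 0.10 (SE; adjusted p = 0.000674), and Acaca and Scd1, enzymes of fatty acid synthesis, by -0.56 ± 0.12 and -0.90 ± 0.21 (adjusted p = 0.00402 and 0.00763). In the club and secretory list 4 were higher and 6 lower of 57 (8 and 12), with Cbr2 at -1.11 ± 0.24, Cyp2f2 at -0.69 ± 0.16, Lcn2 at -0.50 ± 0.13 and Aldh1a1 at 0.39 ± 0.08. RAS-ERK output had 6 higher and 4 lower of 276 (9 and 4), with Epha2 at 0.365 ± 0.07, Dusp5 at 0.25 ± 0.07 and Epha4 at -0.83 ± 0.20. The hypoxia and glycolysis list had 5 and 3 of 235 (5 and 5), with Hif1a at 0.37 ± 0.08, Ldha at 0.49 ± 0.12 and Ndrg1 at 0.25 ± 0.07 and P4ha2 at -0.44 ± 0.11. TGF-beta and SMAD signalling had 3 and 5 of 283 (3 and 4), with Ltbp1 at 0.56 ± 0.16 and Ltbp2 at -0.28 ± 0.08. NF-kB signalling had 1 and 4 of 176 (1 and 3), with Birc3 at -0.34 ± 0.07, Cxcl1 at -0.75 ± 0.21 and Relb at -0.22 ± 0.06, and Ptgs2 at 0.32 ± 0.09, which without the block and the TIGIT-positive library of animal 1 was -0.007.

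The epithelial to mesenchymal list had 2 higher and 3 lower peaks of 150 (6 and 5 adjusted over the list alone), with Tgfbi at 0.47 ± 0.13 and Sparc, Hmga2 and Twist2 at -0.59 ± 0.13, -0.61 ± 0.14 and -0.96 ± 0.27. Epithelial junctions had 4 and 4 of 224 (8 and 4), with Tjp1 and Cldn7 at 0.43 ± 0.11 and 0.34 ± 0.09 and Cldn3 at -0.325 ± 0.09. Basal and squamous genes had 2 and 1 of 69 (4 and 1), with Trp63 at 0.68 ± 0.16, Krt5 at 0.50 ± 0.14 and Pax9 at -0.79 ± 0.20. The neuroendocrine list had 1 and 1 of 62 (1 and 1), with Ncam1 at 0.76 ± 0.23 and Uchl1 at -0.68 ± 0.17. The cell cycle list had 0 and 2 of 81 (0 and 2), near Cdk1 (-0.715 ± 0.21) and E2f2 (-0.57 ± 0.17). The MHC class II and interferon list had 0 and 1 of 61 (0 and 1), at H2-Aa (-0.41 ± 0.09), and the ciliated list 0 of 88 (0 over the list alone). The cell cycle list was called lower with gene-end peaks only and no block, but not with the block. With peaks within 100 kb its adjusted p was 0.861 with an estimated correlation and the block, and 0.979 without the block.

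Each test of an explanation from here on, the counts of splits included, was chosen after the result it measures was seen. Without a block, 35 of the 35 splits of the 8 libraries into 4 and 4 gave at least the 0 calls of the real split, as any split must, so this count says nothing about chance. The highest other split called 3051 peaks, with both libraries of animal 1 and the TIGIT-positive libraries of animals 2 and 4 against the rest, which points to a structure of the samples. With the block, the real split called 3547 peaks and the highest of the other 7 that part all 4 pairs called 0 (1 of 8 as large), and 8 splits are too few for a share under 0.05. The calls may have rested on 1 pair alone, but peaks called from 3 pairs exceeded all tested peaks in their share with the called direction in the left-out pair by at least 16.2 percentage points.

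For the AT2 identity and high-plasticity lists the tables argue against a trend with abundance as the whole cause, since with the block and loess offsets the list medians were -0.102 and 0.133, against -0.104 and 0.135, and both lists stayed called. They also argue against a few genes with many peaks: 16 of 18 AT2 gene means lay below 0 and 17 of 19 high-plasticity gene means above 0. Against 100000 draws of random genes matched on their number of peaks, the permutation p was 2e-05 and 1e-05. The observed mean counts as 1 draw in these p-values, and 1e-05 is the smallest they can give. Other cell types in the TIGIT-positive gate stay open for the AT2 list, since the 384 peaks of the 5 such lists had a median of -0.012 but went both ways (quartiles -0.134 and 0.144), a spread beyond the AT2 median of -0.104. Also open are the state of the sorted cells, which was not tested, correlation between genes, which the draws leave out, since with an estimated correlation the adjusted p was 0.861 for both lists, and GC content, which was not tested.

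The gain at Tigit may come from the tumour cells or from T and NK cells in the TIGIT-positive gate. The 83 peaks near 15 T and NK cell genes had a median log2 fold change of -0.027 (quartiles -0.098 and 0.085). The smallest gain among the 3 Tigit peaks was 0.378. This median cannot decide, since peaks within 100 kb of these genes, called on these same libraries, need not be sites open in lymphocytes. The 2 called peaks of that list, near Ctla4 and inside Cd4, rose by 0.33 and 0.36, and 0 were called lower. These 2 were 2.41% of the list, against 1.56% of all tested peaks called higher. Their SE were 0.10 and 0.11, and a peak with such an SE is called only at about this size of change or more. The likeness of these values to the gains at Tigit therefore decides nothing. They had 10.75 and 9.37 CPM in TIGIT-negative cells and 13.6 and 12 CPM in TIGIT-positive cells. The labels describe the sorted cells as AT2 cells and name no gate against lymphocytes, so a share of such cells in the TIGIT-positive gate stays open.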
